A study of Arabidopsis thaliana with 12 samples.

How the data were processed

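The series measured transcripts by RNA sequencing in shoot tips of Arabidopsis thaliana accession Col-0. Plants were grown on NPA, an inhibitor of polar auxin transport, which gives naked inflorescence stems called pins. Tips of pins without visible bumps were cut, kept in liquid medium with 10 µM NPA, and given either 1 µM of the synthetic auxin NAA or the same medium without it (mock) for 30 or 120 min. The 12 libraries form 4 groups of 3, namely mock and auxin at each time, read from the sample titles. Per the labels' protocols each library is a biological replicate made from a pool of tips, and the replicates with the best RNA integrity among those made were sequenced as paired reads of 100 bases. The protocol also states that treatments were started at different moments so that all tips were collected at 1 time of day.

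The deposited files hold whole-number counts per gene, 1 file per library, not normalized by the authors. Per the labels, reads of low quality, adaptors and ribosomal reads were removed before alignment. The submitters' processing notes name TopHat2 2.0.14, HTSeq 0.9.1 and the TAIR10 genome, with no role or order given for them. The strand setting, the overlap mode and the treatment of multiply mapped reads are not given in the sources used here. Each file lists 32678 genes and 5 summary lines (reads in no feature, ambiguous, not unique and similar), which held 8.4% to 9.37% of all entries and stayed out of library sizes and tests. Since strand use is not stated, counts of genes that overlap a gene on the opposite strand, and of near-identical copies such as SAUR19 to SAUR24, SAUR61 to SAUR68, the allene oxide cyclases and the RBCS genes, are uncertain. Gene names, products and coordinates came from NCBI's annotation of assembly TAIR10.1, matched by locus identifier for 31912 of the 32678 genes. The count files hold no coordinates, so all positions refer to TAIR10.1.

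Library totals ran from 24142312 to 32124556 gene counts, and 21892 to 22384 genes had at least 1 count. At this depth a floor of 3 counts corresponds to 0.0934 to 0.124 CPM (counts scaled to a common library size) in a library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

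Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (19914 genes), scaled by TMM and fitted with glmQLFit over all 12 libraries with 4 group means. The common dispersion was 0.0122. Contrasts were tested 2-sided with glmQLFTest and called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. The 4 contrasts were auxin against mock at 30 min, auxin against mock at 120 min, the difference between those auxin effects (120 min minus 30 min), and mock at 120 min against mock at 30 min. Fold changes are given on the log2 scale with an approximate standard error (SE), and group levels as mean CPM ± SD. This SE is the absolute log2 fold change divided by the square root of the F statistic of glmQLFTest. It was not estimated apart from that test and may be too small for genes with few counts. A gene with no count in 1 group has its fold given as a lower bound against 3 counts over that group, and a gene with 1 to 3 counts there as a ratio of summed counts with an exact interval.

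Gene lists (25 lists, 356 members written by name) covered Aux/IAA repressors, GH3 auxin conjugation, SAUR genes, LBD lateral organ genes, ARF and TIR1/AFB signalling, auxin transport, auxin biosynthesis, HD-ZIP II, floral and organ initiation, shoot meristem and boundary, floral organ identity and flowering time, cytokinin response and metabolism, gibberellin and brassinosteroid metabolism, ethylene synthesis and response, wounding and jasmonate, touch and rapid stress response, low-oxygen response, carbon starvation, cell cycle, cell wall loosening, circadian clock, and markers of photosynthetic tissue, xylem and phloem, epidermis and the stomatal lineage. The members ERF109 and LDH1 were left out because the reference did not give those symbols to the listed loci. SAUR genes were taken by symbol (16 loci). One of them, SAUR21, carries an ARM-repeat product in the reference, so membership by product name (78 loci, 57 tested) was added after the data were seen. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 25 lists of a contrast, and again with an estimated correlation. Members are counted over all genes tested and adjusted over the list alone.

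The design, tests, lists, alternatives and the rule for naming genes were set before the data were examined. Per contrast the rule took, among called genes whose 3 libraries of 1 group all lay above the 3 of the other and whose mean was at least 2 CPM, the 6 highest and 4 lowest fold changes (for the difference, the 5 highest and 5 lowest called genes with a mean of at least 2 CPM). It added the 2 called members with the smallest adjusted p of each list, or 4 for Aux/IAA, SAUR, auxin transport, floral and organ initiation, and shoot meristem and boundary. It always included the genes the protocol tested by qPCR (AHP6, PIN1, ARF5, also called MP, PID and the control AT1G04850) as well as LFY and AINTEGUMENTA, and allowed a gene named in 1 contrast to be given in another. It named 128 genes.

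The procedure was tested on simulated data. Fold changes of 1.5, 2 and 4 were given to seeded genes among 19820. The comparison at 30 min recovered 56.7%, 86.6% and 98.5% of them with 5.85% false calls. The comparison at 120 min recovered 79.1%, 88.1% and 100% with 2.73% false calls. Before the folds each gene had the same level and dispersion in all libraries, so these rates describe no difference between the times. Nor do they cover the larger spread between the real replicates at 30 min. A simulated list of 20 genes raised 1.5-fold among 19821 gave a camera p of 2.33e-38, and 1 of 100 unchanged lists gave a p under 0.05. The simulated genes varied independently, so this does not show how often the preset correlation gives false calls on real lists. Estimated correlations of the real lists at 30 min ran from −0.0448 (floral organ identity and flowering time) to 0.652 (touch and rapid stress).

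Alternatives were DESeq2 size factors, upper-quartile scaling, total count only, no filter, at least 5 CPM in 3 libraries, organellar genes left out, limma-voom, the test of DESeq2 1.42.0, only the libraries compared, the replicate number as a block, an adjusted p under 0.01, a minimum fold of 1.5, and each library left out in turn. Lists were also tested with fry, which does not set the members against the other genes. Promoter hexamers were counted with Python 3.11.15 and tested with Fisher's exact test in SciPy 1.17.1. Plots were drawn with matplotlib 3.10.9.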

Results

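Transcripts of shoot tips from NPA-grown Arabidopsis pins were counted per gene in 12 libraries, 3 each of mock and auxin-treated tips at 30 and at 120 min. A pin is an inflorescence stem that forms no flowers because auxin transport is blocked, and its tip holds the shoot apical meristem. The series was designed to follow the dynamics of early auxin responses in this tissue. Libraries held 25939171 to 32124556 gene counts at 30 min and 24142312 to 31801851 at 120 min, a range in which the times did not separate (exact permutation p = 0.537, 2-sided, 6 libraries against 6). Replicates correlated at 0.98 to 0.993 in log2 CPM. No pair of libraries in a group agreed within sampling noise, so all 12 were kept as separate replicates. Chi-square per degree of freedom was 12.55 to 40.28 between replicates at 30 min and 7.785 to 12.78 at 120 min. Replicate 3 of mock at 30 min lay apart from its group, with 0.0926% of gene counts on chloroplast genes against 0.0232% to 0.0343% in the other 5 libraries of that time.

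The first principal component held 66% of the variance and separated the times. The second held 10.5% and separated auxin from mock within each time. AT1G04850, the gene used as the qPCR control in the protocol, had 112 ± 4.46, 109 ± 3.35, 112 ± 3.1 and 109 ± 9.1 CPM (SD, n = 3 each) in mock and auxin at 30 min and mock and auxin at 120 min.

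**Figure D1:**
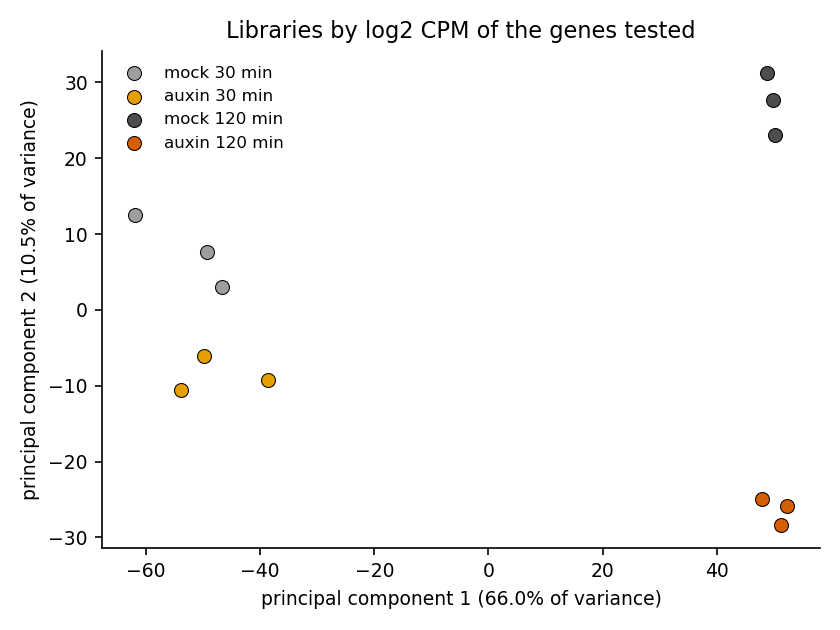
Principal components of log2 CPM of the 19914 genes tested, 1 point per library, with the first component (66% of variance) on the horizontal axis and the second (10.5%) on the vertical axis. The 6 libraries of each time lie on opposite sides of the first component, and at 120 min the 3 auxin libraries lie far from the 3 mock libraries on the second.

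The first comparison asked which genes had responded after 30 min of auxin. ACS8 (AT4G37770), which encodes an enzyme of ethylene precursor synthesis, rose from 1.78 ± 0.336 to 8.21 ± 1.32 CPM, a log2 fold change of 2.20 ± 0.17 (SE, n = 3 per group, adjusted p = 8.6e-05). GH3.2 (AT4G37390), an enzyme that conjugates auxin to amino acids, rose by 2.47 ± 0.34, and LBD16 (AT2G42430), a transcription factor known from lateral root initiation, by 2.04 ± 0.27. TMO5 (AT3G25710), a target of the auxin response factor MONOPTEROS that acts in vascular tissue, rose from 22.5 ± 0.647 to 56.8 ± 8.48 CPM (log2 fold change 1.34 ± 0.09, adjusted p = 6.51e-05). In all, 72 of 19914 genes passed the threshold, 64 higher and 8 lower, and 32 of them changed more than 2-fold. Another split of the same libraries, which mixed mock and auxin, gave 108 genes. The count alone therefore does not set auxin apart from other structure among these libraries. Of the genes called without replicate 3 of auxin at 30 min 51 were higher and 46 lower, and without replicate 2 of mock at 30 min 75.4% of 65 were higher.

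Among these genes ACS8 lies on chromosome 4 (17752079 to 17754157, plus strand), GH3.2 on chromosome 4 (17579618 to 17582022, plus strand), LBD16 on chromosome 2 (17663353 to 17665337, plus strand) and TMO5 on chromosome 3 (9369499 to 9371487, plus strand), all protein-coding in TAIR10.1. Among called genes with a mean of at least 2 CPM and groups that did not overlap, the highest fold change at 30 min was that of AT1G30190, annotated as a cotton fiber protein, which rose from 0.875 ± 0.379 to 6.8 ± 1.58 CPM (log2 fold change 2.97 ± 0.30). PRE5, a small bHLH protein, rose by 2.04 ± 0.21. On the lower side, MYB34, an activator of indole glucosinolate genes, fell by 0.95 ± 0.14 on the log2 scale and MYB4, a repressor of phenylpropanoid genes, by 0.74 ± 0.10. The calls of AT4G24015 (log2 fold change −1.12 ± 0.20, overlapping AT4G24010 on the opposite strand) and XND1 (−0.79 ± 0.14) were lost in 7 and in 4 of the 12 fits that left out 1 library.

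Of the 28 Aux/IAA genes tested, which encode early auxin-induced repressors of the pathway, 7 rose, none fell and 21 did not pass the test over all genes, while 15 rose when adjusted over the list alone. IAA5 rose by 1.79 ± 0.20, IAA1 by 1.73 ± 0.15 and IAA2 by 1.19 ± 0.11 on the log2 scale. IAA5 overlaps AT1G15570 on the opposite strand, so its counts are uncertain. In the HD-ZIP II list, homeodomain factors of shade and auxin responses, 3 of 9 rose (7 adjusted over the list alone), among them HAT2 by 1.17 ± 0.17 and HAT22 by 0.71 ± 0.08. Of 15 SAUR genes, small auxin-induced growth regulators, 2 rose (12 adjusted over the list alone), namely SAUR24 and SAUR20, which are near-identical copies of other SAUR genes and whose calls were lost in 1 and in 5 of the 12 fits that left out 1 library. By product name, 8 of 57 SAUR genes rose (22 adjusted over the list alone). Of 8 GH3 genes 2 rose, GH3.2 and GH3.17 (0.58 ± 0.11, a call lost in 10 of those 12 fits), and adjusted over the list alone 4 rose and 1 fell. In the gibberellin and brassinosteroid list no gene passed over all genes and 3 of 14 rose when adjusted over the list alone.

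These lists stood above other genes in the camera test with adjusted p = 1.04e-35 for Aux/IAA, 1.9e-20 for HD-ZIP II, 1.62e-24 for SAUR, 1.3e-06 for GH3 and 0.0003 for gibberellin and brassinosteroid genes. All 5 calls held with an estimated correlation (adjusted p = 0.00254, 0.000233, 0.0134, 0.0109 and 0.0249 in the same order). The calls of 9 further lists were lost, of which 5 pointed up and 4 down. Floral and organ initiation, where TMO5 and TMO6 rose among 22 genes, had adjusted p = 0.0873 with an estimated correlation. Ethylene synthesis and response, where ACS8 and ACS4 rose among 14 (3 higher and 1 lower adjusted over the list alone), had adjusted p = 0.201 with an estimated correlation. ARF and TIR1/AFB signalling (1 of 20 higher, ARF10) had adjusted p = 0.246 with an estimated correlation, auxin transport (none of 21 called, 1 higher when adjusted over the list alone) 0.235, and floral organ identity and flowering time (none of 11 called) 0.0873. The lists that pointed down included xylem and phloem markers (none of 10 called, median log2 fold change −0.37) and carbon starvation (none of 5 called, 2 lower when adjusted over the list alone), each with adjusted p = 0.235 with an estimated correlation. Wounding and jasmonate (none of 17 called, 0.29) and low-oxygen response (none of 13 called, 0.526) also pointed down. Replicate 3 of auxin at 30 min stood apart for low-oxygen genes, with a mean log2 CPM of 7.03 against 5.48 and 5.69. Without it the list's mean log2 fold change moved from −0.31 to −1.03 (adjusted p = 5.73e-20), and without replicate 1 of that group to −0.06 (0.481). The call was also lost without replicate 2 of that group (adjusted p = 0.243) and without replicate 1 of mock at 30 min (0.428). Without the last library the mean of wounding and jasmonate moved from −0.20 to 0.01 (0.256).

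The other 11 lists did not pass at 30 min, with adjusted p from 0.11 for LBD genes (LBD16 called, 1 of 5) to 0.977 for the shoot meristem and boundary list (none of 16 called). They included cytokinin genes (1 of 15 higher, CKX6, a call lost in 2 of the 12 fits, adjusted p = 0.473), auxin biosynthesis, touch and rapid stress, cell cycle, cell wall loosening, circadian clock and 3 lists of cell type markers, with no member called. The touch list had a mean of −0.08, and it was called lower without replicate 3 of mock at 30 min (−0.29, adjusted p = 0.000923) and higher without replicate 1 (0.18). For LBD genes the median was −0.02 and the mean 0.23, for cytokinin genes the median and mean were −0.05 and −0.11 although the test pointed up, and for photosynthetic markers the median was 0.02 (rounded from 0.015) although the mean and the test pointed down. PIN1, ARF5, PID, LFY, AHP6 and AINTEGUMENTA (AT4G37750) did not pass at 30 min, with log2 fold changes of 0.39 ± 0.18, 0.21 ± 0.09, 0.24 ± 0.11, 0.29 ± 0.13, −0.12 ± 0.58 and 0.10 ± 0.13. None of the 6 passed in the 12 fits that left out 1 library. Their ranges over those fits were 0.20 to 0.67, 0.14 to 0.35, 0.10 to 0.33, 0.20 to 0.38, −0.91 to 0.30 and 0.03 to 0.19. The highest values of PIN1, ARF5, PID and LFY came without replicate 3 of mock at 30 min and the lowest of AHP6 without replicate 3 of auxin at 30 min. The number of genes called at 30 min depended on the fit and the test. It was 13 when only the 6 libraries compared were fitted and 196 with the DESeq2 test. It was 45 without replicate 1 of auxin at 30 min, 36 at an adjusted p under 0.01 and 14 against a minimum fold of 1.5. The main fit shared its dispersions over all 12 libraries, and replicates differed more at 30 min. Its SE and adjusted p at 30 min may therefore be too small.

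The second comparison asked the same at 120 min. Aux/IAA, GH3 and SAUR genes were higher as groups, and genes of jasmonate signalling were lower. ACS8 rose from 0.489 ± 0.0678 to 33.5 ± 4.26 CPM (log2 fold change 6.09 ± 0.19, SE, n = 3 per group, adjusted p = 4.89e-09). GH3.3 rose from 2.73 ± 0.607 to 117 ± 16.4 CPM (5.41 ± 0.36) and IAA19 from 4.75 ± 0.76 to 68.7 ± 9.02 CPM (3.85 ± 0.13). PIN1, the main auxin efflux carrier of the shoot apex, rose from 48.5 ± 6.88 to 142 ± 6.06 CPM (1.55 ± 0.18). JAZ10, a repressor of jasmonate responses that is itself induced by jasmonate, fell by 1.59 ± 0.10 on the log2 scale, from 155 ± 22.5 to 51.4 ± 1.35 CPM. In all, 1243 genes passed, 699 higher and 544 lower, and 371 changed more than 2-fold, 250 up and 121 down.

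**Figure D2:**
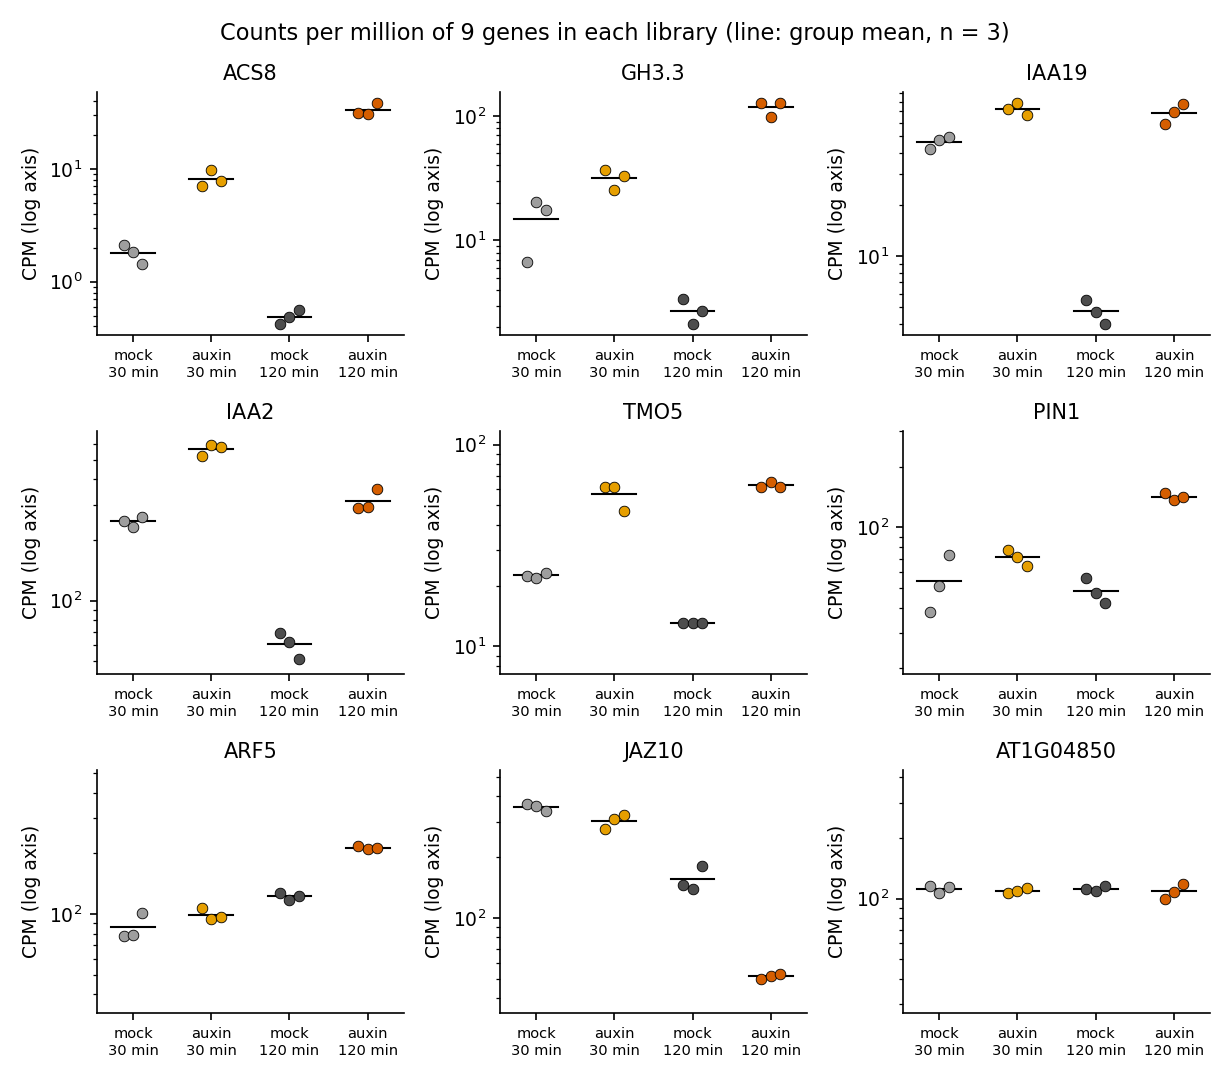
Levels (CPM) of 9 genes in each library on log axes, with 3 points and a line at the mean for each of the 4 groups. ACS8, GH3.3, IAA19, IAA2 and TMO5 were higher with auxin than with mock in all 3 libraries at 120 min, JAZ10 was lower, and the control AT1G04850 had group means of 109 to 112 CPM.

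Some of the largest fold changes at 120 min belonged to genes nearly silent in mock. ACS4 had no counts in the 3 mock libraries and 394 with auxin, at least 139-fold higher against a floor of 3 counts over the group. AT4G13790, a SAUR-like gene, had 2 counts in mock and 547 with auxin, a ratio of 289 (95% counting interval 79.6 to 2390). IAA29 rose from 0.0765 ± 0.0123 to 12.4 ± 2.29 CPM (log2 fold change 7.25 ± 0.38) and GH3.2 by 5.02 ± 0.36. Among called genes with a mean of at least 2 CPM and groups that did not overlap, the lowest values were those of CYP94B1, a cytochrome P450 that oxidizes jasmonoyl-isoleucine (−2.82 ± 0.24), and of FAMT (−2.20 ± 0.50, a call lost in 4 of the 12 fits that left out 1 library). Next came the bHLH gene AT2G40200 (−2.14 ± 0.15) and MYB34 (−2.12 ± 0.16). GH3.3 lies on chromosome 2 (9863855 to 9866562, minus strand), IAA19 on chromosome 3 (5264001 to 5265695, plus strand), PIN1 on chromosome 1 (27659673 to 27663253, plus strand), JAZ10 on chromosome 5 (4218786 to 4221077, plus strand) and CYP94B1 on chromosome 5 (25408821 to 25410725, minus strand). AT2G40200 overlaps AT2G40205 on the opposite strand.

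At 120 min 21 of 28 Aux/IAA genes rose and none fell (22 adjusted over the list alone), with a median log2 fold change of 1.28. IAA1 rose by 3.21 ± 0.16 and IAA2 by 2.37 ± 0.12. Of 15 SAUR genes 13 rose (13 adjusted over the list alone), with a median of 1.66, among them SAUR26 by 2.37 ± 0.23 and SAUR24 by 2.08 ± 0.20, and by product name 27 of 57 rose (31 higher and 1 lower adjusted over the list alone). Of 8 GH3 genes 4 rose (5 adjusted over the list alone), with a median of 1.38. HD-ZIP II had 3 of 9 higher (5 adjusted over the list alone), including HB17 by 4.88 ± 0.33 and HAT2 by 2.39 ± 0.17. In auxin transport 9 of 21 rose (11 adjusted over the list alone), among them LAX2, an auxin influx carrier, by 2.86 ± 0.21, PIN6 by 1.17 ± 0.15 and PIN4 by 1.11 ± 0.17. In ethylene synthesis and response 5 of 14 rose (6 adjusted over the list alone), with a median of 0.49 that was the same with ACS4 at its bound.

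In the floral and organ initiation list 6 of 22 genes rose and 1 fell (9 and 1 adjusted over the list alone). TMO5 rose by 2.27 ± 0.10, HB-8, a vascular HD-ZIP III gene, by 1.56 ± 0.16, TMO6 by 1.19 ± 0.11 and ARGOS, a regulator of organ size, by 1.09 ± 0.16. These 4 had the smallest adjusted p of the list, so a call of the list does not by itself show a rise of floral genes. LFY, the floral meristem identity gene, rose from 7.25 ± 0.981 to 10.1 ± 0.557 CPM (log2 fold change 0.48 ± 0.13, adjusted p = 0.0378), a call lost in 5 of the 12 fits that left out 1 library. AINTEGUMENTA (AT4G37750) had a log2 fold change of 0.26 ± 0.13 (adjusted p = 0.307, and 0.12 without replicate 2 of mock at 120 min), and AHP6, measured at under 1 CPM in every group, 1.56 ± 0.56 (adjusted p = 0.143). ARF5, which encodes MONOPTEROS and overlaps AT1G19860 on the opposite strand, rose by 0.80 ± 0.09 and PID, a kinase that acts on PIN proteins, by 0.56 ± 0.11. In the shoot meristem and boundary list HEC1 (1.42 ± 0.27) and STM (0.33 ± 0.08, lost in 4 of those 12 fits) rose among 16.

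In the wounding and jasmonate list 12 of 17 genes fell and none rose (14 fell adjusted over the list alone), with a median log2 fold change of −1.05 (rounded from −1.055). JAZ9 fell by 1.67 ± 0.12 on the log2 scale. In the touch and rapid stress list TCH3 (0.78 ± 0.12) and WRKY33 (0.75 ± 0.17, lost in 4 of the 12 fits that left out 1 library) rose among 9, and the list had adjusted p = 0.41 with an estimated correlation. Of 17 cell wall loosening genes 6 rose, including EXPA10 (1.69 ± 0.22) and XTH19 (1.54 ± 0.23), and 2 fell only when adjusted over the list alone. That list had adjusted p = 0.0509 with an estimated correlation. In hormone metabolism 3 of 14 gibberellin and brassinosteroid genes rose and 3 fell, with DWF4, a brassinosteroid synthesis enzyme, down by 1.45 ± 0.12 and BAS1, which inactivates brassinosteroids, up by 2.00 ± 0.19. Among 15 cytokinin genes 2 rose, CKX6 (1.81 ± 0.16) and ARR7 (1.45 ± 0.25), and 2 fell. Counts of CKX6, WRKY33 and LUX are uncertain, since each overlaps a gene on the opposite strand.

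With an estimated correlation the calls of 8 lists held at 120 min, with adjusted p = 0.000208 for Aux/IAA, 0.000799 for GH3, 0.00409 for SAUR, 0.0227 for auxin transport, 0.00173 for HD-ZIP II, 0.0114 for floral and organ initiation, 0.0053 for ethylene and 0.00318 for wounding and jasmonate. The calls of cell wall loosening, touch and rapid stress, circadian clock and carbon starvation were lost. In the clock list 2 of 13 were lower (LUX and CCA1, adjusted p = 0.322 with an estimated correlation) and in carbon starvation 1 of 5 (TPS8, 0.324). With fry the adjusted p was 0.00292 for cell wall loosening, 0.119 for touch, 0.0329 for the clock and 0.0554 for carbon starvation. The other 13 lists did not pass, from an adjusted p of 0.0757 for LBD genes (1 of 5 higher, LBD16) to 0.967 for the shoot meristem list and for floral organ identity and flowering time (SPL9 higher and SOC1 lower of 11). Among them were ARF and TIR1/AFB signalling (6 of 20 higher and 2 lower), auxin biosynthesis (1 of 6 higher, YUC3), and low-oxygen response (1 of 13 higher, SUS1). They also included cell cycle (2 of 29 higher, 2 lower, among them MCM5 and KRP2) and the 4 marker lists, in which RBCS1B was the single gene called of 8, 10, 6 and 6. In the 12 fits that left out 1 library the calls of RBCS1B and SPL9 were lost in 9, TPS8 in 8, CCA1 in 7, SUS1 in 5, SOC1 in 4 and MCM5 in 2. Of the lists not called, 5 were called in some of those fits, the LBD list in 4. The median for low-oxygen genes was −0.09 with a mean of 0.09, and for flowering genes the median was 0.03 and the mean 0.06 although the test pointed down. The number of genes called at 120 min was 2095 when only the 6 libraries compared were fitted and 776 without replicate 3 of auxin at 120 min. It was 698 at an adjusted p under 0.01 and 268 against a minimum fold of 1.5. Since replicates differed less at 120 min, the shared dispersions may make SE and adjusted p at that time too large.

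**Figure D3:**
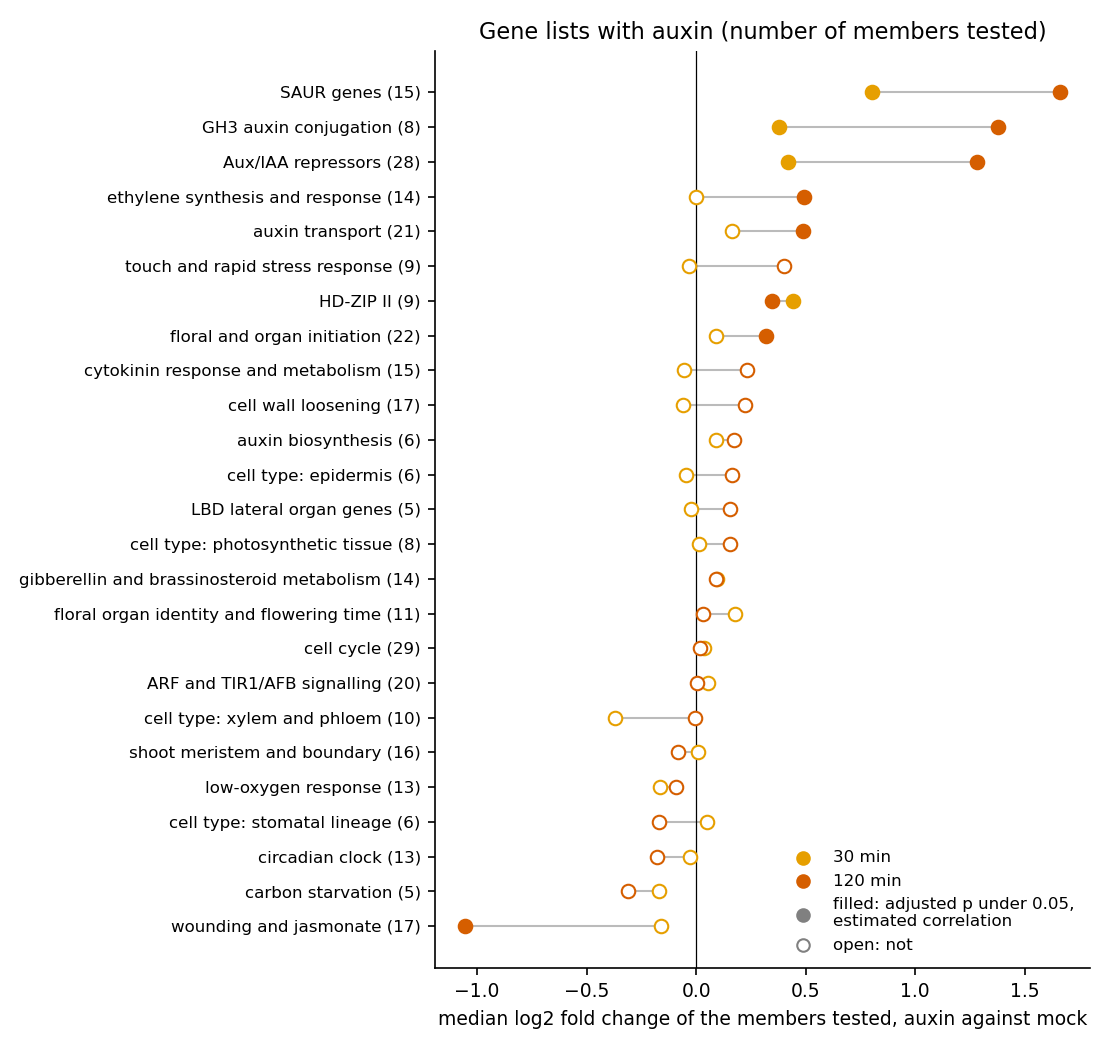
Median log2 fold change, auxin against mock, of the tested members of each of 25 gene lists at 30 and 120 min, with the number of members in brackets. Filled points have an adjusted p under 0.05 with an estimated correlation. SAUR, GH3 and Aux/IAA genes had medians of 1.66, 1.38 and 1.28 at 120 min, and wounding and jasmonate genes −1.05.

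The third comparison asked whether the auxin effect itself differed between the times. As groups, Aux/IAA, GH3 and SAUR genes had a larger effect at 120 min, and wounding and jasmonate genes a more negative one. From 30 to 120 min the mean log2 level of Aux/IAA, GH3 and SAUR genes changed by −0.67, −0.95 and −1.16 in mock. In auxin-treated tips it changed by 0.49, 0.4 and −0.23, so much of the larger effect on these genes lies in mock. ACS8 had a log2 fold change of 2.20 at 30 min and 6.09 at 120 min, a difference of 3.89 ± 0.27 (SE, n = 3 per group, adjusted p = 3.06e-05). IAA19 differed by 3.2 ± 0.17 (adjusted p = 2.68e-06), GH3.3 by 4.32 ± 0.45 and LAX2 by 2.58 ± 0.29. JAZ10 differed by −1.37 ± 0.14 and CYP94B1 by −2.35 ± 0.30. The difference passed for 192 genes, 120 with a higher and 72 with a lower effect at 120 min.

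Among lists, 12 of 28 Aux/IAA genes (17 adjusted over the list alone), 3 of 8 GH3 genes (4), and 1 of 15 SAUR genes (9) had a higher effect at 120 min, with counts adjusted over the list alone in brackets. So had 2 of 14 ethylene genes (5) and 1 of 17 cell wall loosening genes (5), and 5 of 17 wounding and jasmonate genes (12) had a lower one. Their median log2 differences were 0.64, 1.05, 0.95, 0.56, 0.37 and −0.91 (rounded from −0.905) in that order. These 6 calls held with an estimated correlation, at adjusted p = 0.00187, 0.00234, 0.0486, 0.014, 0.0292 and 0.00575. Auxin transport (LAX2 and PIN6 higher of 21, adjusted p = 0.0752 with an estimated correlation), floral and organ initiation (TMO5, HB-8 and ARGOS higher of 22, 0.0799), touch and rapid stress (0.429), low-oxygen response (0.459) and epidermis markers (0.429) lost theirs, the last 3 with no member called. The other 14 lists did not pass, with adjusted p from 0.0679 for xylem and phloem markers to 0.954. Of these, 7 were called in some of the 12 fits that left out 1 library, xylem and phloem markers in 5 and circadian clock in 4. HAT2 and HB17 of the HD-ZIP II list had higher effects and DWF4 a lower one (−1.45 ± 0.17). Of the 26 named genes that were called in this comparison, 16 kept their call in every fit that left out 1 library. EXPA15 lost its call in 11 of the 12, ACS6 in 10, and PIN6, ARGOS and NAI1 in 9. HAT2 and AT4G13790 lost theirs in 8, SAUR15 and AT3G27970 in 6 and HMT3 in 4. The mean difference of low-oxygen genes was 0.40, and 1.12 without replicate 3 of auxin at 30 min and 0.15 without replicate 1, and its call was lost in 7 of the 12. The median and mean differed in sign for HD-ZIP II (−0.09 and 0.42), ARF and TIR1/AFB signalling (−0.05 and 0.05), gibberellin and brassinosteroid genes (−0.05 and 0.07) and the shoot meristem list (0.03 and −0.08). PIN1 differed by 1.16 ± 0.25 (adjusted p = 0.0541), ARF5 by 0.59 ± 0.13 (0.065), PID by 0.32 ± 0.16 (0.538) and LFY by 0.20 ± 0.18 (0.819), none past the threshold. Leaving out 1 library gave 0.23 to 0.47 for PID and 0.10 to 0.31 for LFY, with PID highest without replicate 1 and LFY lowest without replicate 3 of mock at 30 min and highest without replicate 3 of mock at 120 min. PIN1 and ARF5 passed without replicate 1 of mock at 30 min (1.35, adjusted p = 0.00557, and 0.65, 0.0331) and without replicate 3 of it (0.88 and 0.45). The number of genes called was 473 with the DESeq2 test, 61 at an adjusted p under 0.01 and 26 against a minimum fold of 1.5. Leaving out 1 library lowered it to between 92 and 120 for 6 of the 12 libraries, lowest without replicate 3 of auxin at 120 min.

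Across the 19914 genes the fold changes at 30 and 120 min correlated at r = 0.307, a description across genes that are not independent replicates, and at 0.756 over the 1246 genes called at either time. All 64 genes higher at 30 min were also called higher at 120 min, against 2.25 for independent lists, and 5 of the 8 lower genes were also lower, against 0.22. The median log2 fold change of the 64 genes was 0.93 at 30 min and 1.80 at 120 min. The comparisons at the 2 times share no library, but they share the dispersions of 1 fit. A gene with a low dispersion is more easily called at both times, so 2.25 and 0.22 are a guide and not a chance expectation. Without replicate 1 of mock at 30 min r was 0.166.

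**Figure D4:**
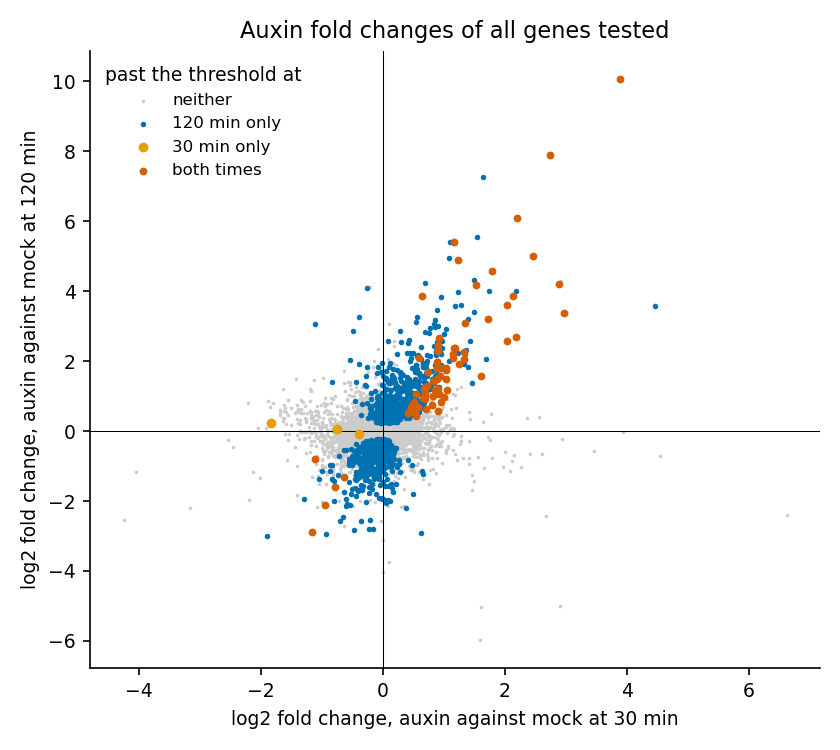
Fitted log2 fold changes of auxin against mock at 30 min (horizontal) and at 120 min (vertical), 1 point per gene tested, coloured by the times at which the gene passed the threshold. Values of genes with few counts, such as ACS4 at the top, depend on the fit and are not bounds.

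The last comparison asked how mock tips changed between 30 and 120 min. Many genes of touch, wounding and low-oxygen responses were lower at 120 min, and several meristem genes were higher. LOX3, a lipoxygenase of jasmonate synthesis, fell from 805 ± 96.3 to 104 ± 21.7 CPM (log2 fold change −2.95 ± 0.15, SE, n = 3 per group, adjusted p = 2.71e-08). TCH3, a touch-induced calcium-binding protein, fell from 1220 ± 226 to 340 ± 15 CPM (−1.85 ± 0.12) and ARR7, a cytokinin-induced response regulator, from 40.9 ± 6.88 to 3.22 ± 1.14 CPM (−3.66 ± 0.24). FKF1, a clock-controlled photoreceptor that overlaps AT1G68060 on the opposite strand, rose by 4.07 ± 0.20 and KNAT1, a homeobox gene of the meristem, by 1.06 ± 0.08. In all, 10071 genes (50.6%) passed, 4863 higher and 5208 lower, of which 910 and 1700 changed more than 2-fold.

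By the same rule as above the highest values were those of AT1G66830 (4.65 ± 0.36), FKF1, LCR67, a small cysteine-rich protein (4.03 ± 0.26), AT5G52390 (3.97 ± 0.28), AT3G13610 (3.92 ± 0.94) and AT5G23240 (3.69 ± 0.28). The lowest were those of SRO4 (−6.90 ± 1.84), MSRB6 (−6.57 ± 0.56), NIP2;1 (−5.99) and AT3G01202 (−5.68 ± 0.52). AT1G66830, AT3G13610, SRO4, NIP2;1 and AT3G01202 overlap a gene on the opposite strand. ACS4 was at least 5.36-fold lower and GA2OX8 at least 9.78-fold lower at 120 min, where neither had a count. LOX3 lies on chromosome 1 (5977323 to 5981521, plus strand), TCH3 on chromosome 2 (17137037 to 17139700, plus strand), ARR7 on chromosome 1 (6577833 to 6579314, minus strand) and KNAT1 on chromosome 4 (5147699 to 5151159, minus strand).

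All 9 touch and rapid stress genes fell (median log2 fold change −1.85), as did 10 of 13 low-oxygen genes (median −2.64), and 13 of 17 wounding and jasmonate genes fell and 2 rose (median −1.20). Examples are XTH22 (log2 fold change −2.30 ± 0.22), HRE1 (−2.64 ± 0.27, overlapping AT1G72370 on the opposite strand) and AOC3 (−2.13 ± 0.11, a near-identical copy of other cyclase genes). Of the Aux/IAA genes 14 fell and 5 rose of 28, with IAA6 down by 5.13 ± 0.29 and IAA19 by 3.28 ± 0.13. Of the SAUR genes 12 fell and 1, SAUR36, rose of 15 (by product name 28 fell and 9 rose of 57), of the HD-ZIP II genes 6 of 9 fell, and of the cytokinin genes 10 fell and 1 rose of 15. In the shoot meristem and boundary list 10 of 16 rose and 1 fell, with PNF up by 1.26 ± 0.15. In floral organ identity and flowering time 7 of 11 rose and 1 fell, with SVP up by 1.31 ± 0.14 and SOC1 by 0.82 ± 0.07. Of 13 clock genes 4 rose, among them ELF4 (3.18 ± 0.32) and GRP7 (1.77 ± 0.08), and 4 fell. Adjusted over the list alone the counts in these lists were the same, except for 6 Aux/IAA and 11 meristem genes higher and 29 SAUR genes by product name lower. None of the list calls in this comparison held with an estimated correlation (adjusted p = 0.0776 or above). With fry the adjusted p was 3.11e-06 for wounding and jasmonate, 0.000179 for touch and 0.00134 for low-oxygen genes. Since 50.6% of all genes were called in this comparison, the fry result does not set these lists apart from other genes.

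The camera test called 11 lists in mock tips, namely the 9 of these other than the clock, ethylene synthesis and response (2 of 14 higher, 8 lower) and ARF and TIR1/AFB signalling (11 of 20 higher, 3 lower). The adjusted p of the last rounds to 0.05, and its call was lost in 7 of the 12 fits that left out 1 library. The adjusted p with an estimated correlation was 0.0776 for wounding and jasmonate and for HD-ZIP II, 0.105 for flowering, 0.2 for the shoot meristem list and for cytokinin, 0.212 for touch, 0.258 for Aux/IAA, 0.376 for SAUR, low-oxygen and ARF and TIR1/AFB genes and 0.385 for ethylene. The other 14 lists did not pass, with adjusted p from 0.0633 to 0.891. They were cell wall loosening (4 higher, 9 lower of 17, a list called in 6 of those 12 fits), LBD (3 higher of 5), and cell cycle (9 higher, 3 lower of 29). The same held for gibberellin and brassinosteroid (8 higher, 2 lower of 14), GH3 (1 higher, 4 lower of 8), auxin transport (6 higher, 3 lower of 21), auxin biosynthesis (2 higher, 3 lower of 6), and floral and organ initiation (5 higher, 6 lower of 22). Carbon starvation (2 lower of 5) and circadian clock did not pass either, nor did the markers of photosynthetic tissue (3 higher, 3 lower of 8), xylem and phloem (3 lower of 10), epidermis (1 higher, 1 lower of 6) and stomatal lineage (2 higher, 1 lower of 6). The clock list had a median of −0.05 and a mean of 0.19, auxin transport −0.02 and −0.06 although the test pointed up, and floral and organ initiation a median of 0.02 and a mean of −0.10.

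The libraries of the 2 times also differed in make-up. The number of genes detected differed (22200 against 22000 on average). Reads in no feature were 2.41% on average at 30 min (2.23% to 2.52%) and 1.99% at 120 min (1.79% to 2.05%). Chloroplast genes held 0.038% and 0.0167% of gene counts. All 3 measures had an exact permutation p = 0.00216 (2-sided, 6 libraries against 6, adjusted p = 0.00432 over 6 measures). For mock at 120 min against mock at 30 min the split between higher and lower genes depended on scaling, with 6595 higher and 4147 lower with the total count only and 5809 higher and 4568 lower with upper-quartile scaling, against 4863 and 5208 with TMM. Against a minimum fold of 1.5 the number called was 2727.

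**Figure D5:**
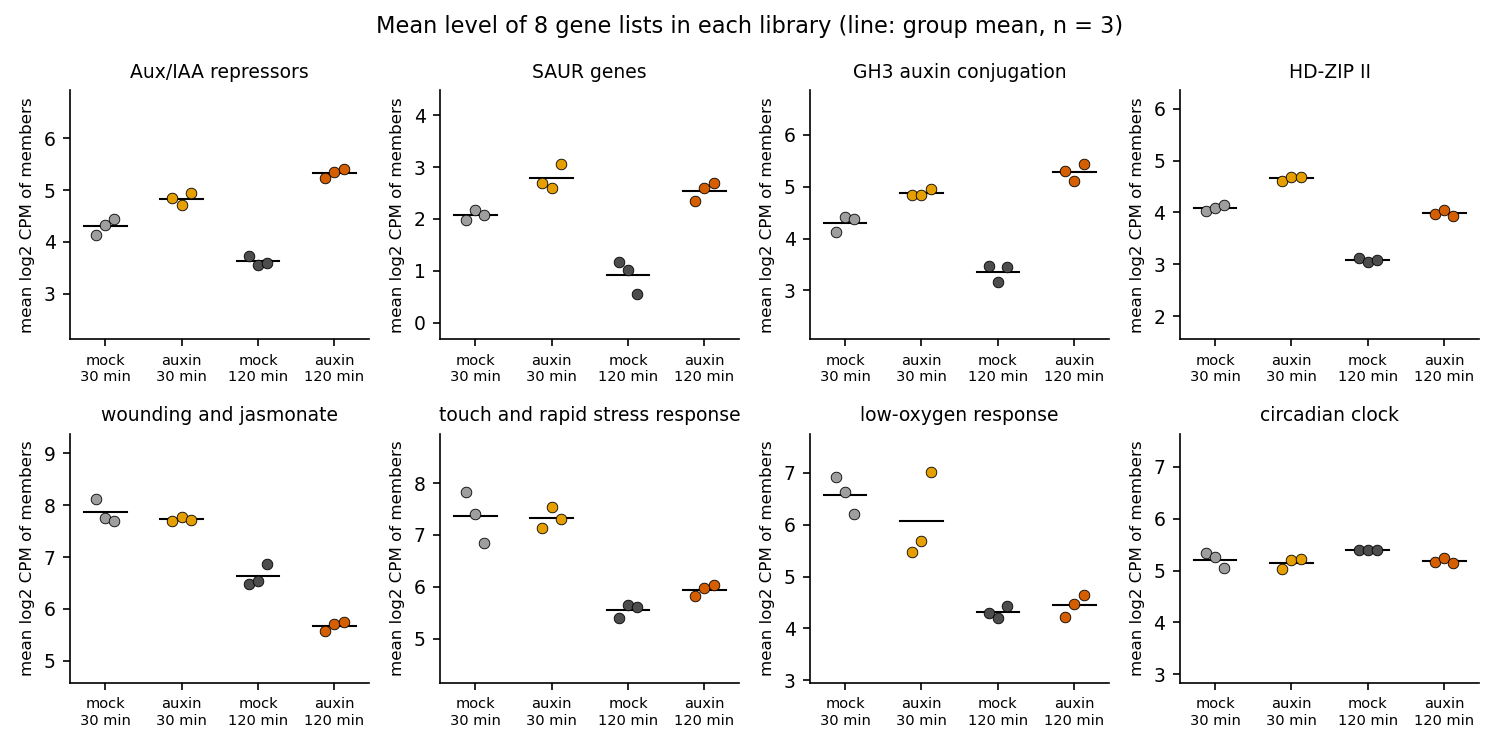
Mean log2 CPM of the members of 8 gene lists in each library, with 3 points and a line at the mean for each of the 4 groups. Touch and low-oxygen genes were lower in all 6 libraries at 120 min than in the 6 at 30 min, and Aux/IAA genes were lowest in mock at 120 min and highest with auxin at 120 min.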

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

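The test of the difference between times, the list tests, other scalings and leaving out single libraries were set before the data were examined, and the other tests in this part were chosen only after the result was seen. The auxin effect differed between 30 and 120 min for 192 genes and for 6 gene lists, by the test of that difference. The called genes among those named by the rule are given with the log2 difference, 120 min minus 30 min. The effect was higher at 120 min for IAA29 (5.61), GH3.3 (4.32), IAA6 (4.23), ACS8 (3.89), HB17 (3.66), IAA19 (3.2), IAA5 (2.79), LAX2 (2.58), GH3.5 (1.45), HB-8 (1.39) and TMO5 (0.93). It was lower for CYP94B1 (−2.35), AOC1 (−1.92, counts shared with near-identical copies), JAZ9 (−1.49), DWF4 (−1.45) and JAZ10 (−1.37). These 16 calls were kept in every fit that left out 1 library. The other 10 were lost in some of the 12 fits, namely AT4G13790 (5.16, range 4.59 to 7.76, fitted values that depend on the prior count since mock at 120 min held 2 counts), SAUR15 (2.31, range 2.01 to 2.67), ACS6 (1.28, range 1.01 to 1.51), HAT2 (1.22, range 0.95 to 1.39), ARGOS (1.07, range 0.81 to 1.18), PIN6 (1.03, range 0.83 to 1.20), and EXPA15 (0.92, range 0.77 to 1.02). The lower ones were HMT3 (−2.35, range −2.87 to −2.08), AT3G27970 (−1.90, range −2.12 to −1.61) and NAI1 (−1.85, range −2.07 to −1.52). The median differences of the lists were 0.64 for Aux/IAA, 1.05 for GH3, 0.95 for SAUR, 0.56 for ethylene synthesis and response, 0.37 for cell wall loosening and −0.91 (rounded from −0.905) for wounding and jasmonate. In 100 random splits of the libraries, 11 gave as many genes, the real one included, and the highest other gave 1232. The 10 others all kept the real auxin and mock groups of 120 min and with them the effect at that time, so these splits do not decide whether chance can be excluded. Of the 89 that mixed those groups the highest gave 5.

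The first pattern is the larger auxin effect on Aux/IAA and SAUR genes at 120 min, where the mean log2 level of Aux/IAA genes changed by −0.67 (SE 0.10) in mock from 30 to 120 min and by 0.49 (SE 0.09, 13 of 28 genes higher and 6 lower) in auxin-treated tips, and that of GH3 genes by −0.95 (SE 0.13) and 0.40 (SE 0.10, 5 of 8 higher and 2 lower), so that much of each difference lies in mock. Between the times in auxin-treated tips 9491 of all 19914 genes were called, 4657 higher and 4834 lower. A rise there is therefore not by itself a response to auxin. A fall in mock alone does not give the rise of the Aux/IAA and GH3 means in auxin-treated tips. It may account for IAA6 (difference 4.23, mock change −5.13) and IAA19 (3.2 and −3.28). Other scalings left the mean difference of Aux/IAA genes at 1.21 or above, which argues against scaling. Members with a mean of at least 10 CPM had a mean difference of 0.88 ± 0.22 (SE over 20 members, which are not independent replicates). That is below the 1.23 of all 28 members. It argues against folds of genes with few counts as the whole of the difference, though they may add to it. In auxin-treated tips the mean level changed by −0.23 (SE 0.17) for SAUR, 0 (SE 0.15) for ethylene and −0.04 (SE 0.07) for cell wall loosening genes, against −1.16, −0.85 and −0.52 in mock, so a fall in mock may account for these differences. A biological candidate for Aux/IAA genes is a response that builds up with time in auxin, which these tests leave open as a hypothesis.

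The second pattern is the lower level of wounding and jasmonate genes with auxin at 120 min. The lowest median of the 4 marker lists was −0.17, which argues against another share of those cell types in the cut tips. The touch list, which also fell in mock over time, had a median of 0.4 with auxin, which goes against auxin-treated tips being further along in the same fall. This gauge is weak, since TCH3 and WRKY33 of that list rose with auxin and its camera call was lost with an estimated correlation (adjusted p = 0.41). Among other stress lists whose mean fell in mock, low-oxygen genes had a median of −0.09 with auxin at 120 min and carbon starvation genes −0.31. The explanation is therefore not excluded. The list's mean stayed at −0.835 or below without each library in turn, so no single library gave it. An effect of auxin on jasmonate signalling may be the cause and was not tested apart from its transcripts.

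The third pattern is the difference between the mock groups, with 50.6% of genes called. All 8 of the 8 clock genes called moved as a later time of day gives, while 5 of 13 were not called. Of these, TOC1 (−0.12), LUX (−0.05) and BOA (−0.34), which a later time would raise, had log2 changes below 0. GI (0.18) and PRR7 (0.17) had changes above 0. The labels state that treatments were started so that all tips were harvested together. Of the touch, wounding and jasmonate and low-oxygen genes 82.1% were lower at 120 min, as a faded response to cutting and transfer would give. The labels do not give the time since cutting for each group. None of these list calls held in camera with an estimated correlation (adjusted p = 0.212, 0.0776 and 0.376 in that order). The share was chosen after the fall of these lists was seen, so it restates that fall. The share of reads in no feature separated the times (exact permutation p = 0.00216, 6 libraries against 6), but the labels name no batch, so libraries prepared apart cannot be told apart from time. These explanations may hold together, and a biological difference between tips held for different times stays open.

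The other counts have too few splits, 10 for 3 libraries against 3, for a share under 0.05. With auxin at 120 min the real split gave 1243 genes and the highest other 0, with 1 split of 10 as large. Between the mock groups the real split gave 10071 and the highest other 0, again 1 of 10. With auxin at 30 min 2 of 10 gave as many, with 72 genes in the real split and 108 in the highest other, which set replicates 1 and 2 of mock and 3 of auxin against the rest. That split points to a structure among the libraries of 30 min beside auxin.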

How the results depend on the processing

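The alternatives were chosen before the data were examined, except SAUR membership by product name, chosen after. With auxin against mock at 30 min the count of 72 became 36 at an adjusted p under 0.01, 14 at a minimum fold of 1.5, 13 with only the libraries compared and 196 with the DESeq2 test. It ranged from 45 (without auxin_30min replicate 1) to 97 (without auxin_30min replicate 3, 51 higher and 46 lower) when 1 library was left out. With auxin against mock at 120 min the count of 1243 became 698, 268 and 2095 under the first 3 of these, and ranged from 776 (without auxin_120min replicate 3) to 1663 (without mock_30min replicate 3). For the auxin effect at 120 min against 30 min the count of 192 became 61 at an adjusted p under 0.01, 26 at a minimum fold of 1.5 and 473 with the DESeq2 test. It ranged from 92 (without auxin_120min replicate 3) to 272 (without mock_30min replicate 1). It was also 120 without auxin_30min replicate 2, 109 without mock_120min replicate 2, 107 without mock_120min replicate 3, 107 without auxin_120min replicate 1 and 109 without auxin_120min replicate 2. For mock at 120 min against mock at 30 min the count of 10071 became 2727 at a minimum fold of 1.5 and ranged from 8851 to 10105. The correlation of fold changes at 30 and 120 min was 0.756 over genes past the threshold at either time and 0.471 at 5 CPM in 3 libraries, and ranged from 0.166 (without mock_30min replicate 1) to 0.324 (without mock_30min replicate 3). The list touch and rapid stress response: auxin against mock at 30 min had a mean log2 fold change of −0.08 that ranged from −0.286 (without mock_30min replicate 3, adjusted p = 0.000923) to 0.177 (without mock_30min replicate 1, adjusted p = 0.0381), where its sign reversed. A minimum fold and a lower threshold can only remove calls, and for the rest the cause was not tested. Without mock_30min replicate 3, which stood apart, the 30 min count was 91 and the difference 225. Over all alternatives the named genes gave 2935 results on the same side of the threshold, 192 weaker, 9 stronger and 0 reversed, and the lists 1480, 80, 43 and 1.

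With the replicate block the counts were 44 at 30 min and 116 for the auxin effect at 120 min against 30 min. The numbers do not pair the libraries: deviations of libraries with the same number correlated at −0.25 to 0.12 and those of other numbers at −0.13 to 0.28, and 0 of 12 libraries correlated best with their own number.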

Other observations

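The product families in this part and their tests were chosen only after the data were seen, while the motifs were chosen before their result. Over 184 families grouped by annotated product, the Dof zinc-finger transcription factors had 4 of 18 members higher with auxin at 120 min (adjusted p = 0.000359, and 0.608 with an estimated correlation). The major facilitator transporters had 18 of 97 lower and 3 higher (0.000233, and 0.672 with an estimated correlation). In mock over time, 30 of 45 TIR-NBS-LRR disease resistance genes fell and 2 rose (1.34e-05, and 0.987 with an estimated correlation), 18 of 30 histone genes fell and 2 rose (0.000163, and 0.987), and 10 of 15 berberine-bridge FAD-binding genes rose and 2 fell (0.00106, and 0.987). The SAUR-like family (27 of 57 higher at 120 min, 8.12e-29) and the GH3 family (4 of 11 higher, 4.8e-08) also lost their calls with an estimated correlation, each at adjusted p = 0.153, and at 30 min with 0.381 and 0.345. The shorter SAUR and GH3 lists kept theirs at both times, but they were adjusted over the gene lists of a contrast and not over 184 families. The outcomes of the lists and the families are therefore not comparable. They do not show that the wider SAUR and GH3 membership loses its call through correlation alone. No call of these families held with an estimated correlation.

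Binding sites of auxin response factors were tested as a hypothesis for the genes that rose. The hexamer TGTCGG lay within 500 bp upstream of 12.5% of the genes higher at 120 min and 8.33% of the other genes tested (odds ratio 1.57, 95% interval 1.23 to 1.98, Fisher's exact p = 0.000301, adjusted p = 0.00361 over 12 tests), while the reversed hexamer had an odds ratio of 0.897. Direct targets among those genes would give this and stay a hypothesis. Unlike TGTCGG the reversed hexamer holds no CG pair, so it does not control for the share of such pairs upstream. The test also counted genes as independent, although related copies such as SAUR genes were among them. For genes higher at 30 min the odds ratio was 1.77 (0.768 to 3.62, exact p = 0.113). The prediction written before counted an exact p of 0.05 or more as evidence against the motif, and that reading was changed after the value was seen, because the interval over 64 genes holds both 1 and the odds ratio of 120 min, so the test is left undecided. TGTCTC at 120 min had an odds ratio of 1.23 (1.03 to 1.47, exact p = 0.0219). It met its prediction before adjustment and was likewise left undecided after the value was seen, because its adjusted p over the 12 tests is 0.131.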
